A study of Rattus norvegicus with 9 samples.

How the data were processed

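RNA-seq was analysed for 9 libraries of rat thoracic aortic smooth muscle cells, 3 each of empty-vector cells with BSA, empty-vector cells with AGEs, and CTSD-overexpressing cells with AGEs. The study also set up groups without a vector, which are not analysed here. Per the labels, mRNA was captured on poly-T beads, libraries were made with a NEBNext Ultra kit and sequenced as 150-base read pairs on an Illumina NovaSeq, and reads were aligned to a reference genome. The deposited values are FPKM, fragments per kilobase of gene model, scaled to the fragments assigned to genes, as the authors computed them. The aligner and the annotation release are not given in the sources used here. The authors' notes name a mouse build, mm10, while the deposited gene identifiers and positions are those of rat. Positions are therefore given as deposited, without a build.

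The table lists 32792 genes, 32623 with rat Ensembl identifiers and 169 loci without one. FPKM times gene length came in whole steps in each library, which gave the number of fragments. Between 99.36% and 99.55% of values under 200 fragments lay within 0.1 of a whole number. The libraries so worked out held 4492980 to 5342332 assigned fragments. A 1-kilobase gene with 3 fragments had an FPKM of 0.562 to 0.668.

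Genes with at least 1 FPKM in at least 3 of the 9 libraries were tested, 8532 genes. Values were taken as log2(FPKM + 1) with no further scaling, so fold changes of genes near 1 FPKM are smaller than the ratio of their means. A model with 1 mean per group was fitted to all 9 libraries with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance and two-sided moderated tests. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, within each contrast. The contrasts were AGEs against BSA in empty-vector cells, CTSD against empty vector under AGEs, and, as a further one that the study's text does not list, CTSD under AGEs against empty vector with BSA. The p-values measure the spread between libraries, which may be technical. For Ctsd an exact two-sided permutation test of 3 against 3 libraries stands beside the model.

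The contrasts, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. The genes named in each of the first 2 contrasts are Ctsd, the 10 with the largest rise and the 10 with the largest fall among called genes with a symbol, a mean of at least 1 FPKM in the higher group and no overlap between groups, and from each list up to 4 called members with the largest change. Where a list had no called member, up to 2 members with the highest mean are given as values. The lists cover glycolysis, mitochondrial oxidation, contractile and synthetic smooth muscle, osteogenic and chondrogenic genes, lysosome and autophagy, AGE binding and detoxification, inflammation and NF-kB, oxidative stress (NRF2), interferon response, cell cycle, hypoxia, endoplasmic reticulum stress, cholesterol synthesis, matrix remodelling, and immediate early and heat shock genes. Further lists hold markers of endothelial, adventitial fibroblast, macrophage, epithelial or mesothelial, adipocyte and Schwann or neural cells, and the mitochondrial genome. They were written from general knowledge, 407 entries of which 395 matched the table, 2 of them through an older symbol. Lists with 5 or more tested members were tested with limma camera at its preset correlation between genes, adjusted over the lists of a contrast, and again with the correlation estimated from the data and with fry, which asks whether the members of a list move on balance 1 way.

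Residuals of libraries with the same replicate number in the empty-vector BSA and AGEs groups were correlated (0.14, 0.14 and 0.15), so replicate was added as a block in an alternative and its value is given for named calls that it ended. For CTSD against empty-vector AGEs the correlations were 0.08, -0.03 and 0.07. The alternatives tried were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, the replicate block, fits of 2 groups alone and leaving out each library in turn. After seeing the data, limma voom on the recovered fragments, gene models of at least 200 bases, removal of trends with gene length and with gene density, and list tests without empty-vector AGEs replicate 3 were added.

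The model was tested on simulated data with known changes in 200 genes per contrast. It recovered 62.7%, 76.1% and 97% of genes changed 1.5-fold, 2-fold and 4-fold in the AGEs contrast, with 11 unchanged genes called, and 56.7%, 86.6% and 98.5% in the CTSD contrast, with 6. All simulated genes had the same spread beyond counting (dispersion 0.00281), with no deviating library and no trend with gene length or density. The real data may therefore give lower recovery and more false calls. Tables were prepared with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9. A base composition of genes was not computed, since no genome sequence was used.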

Results

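RNA was sequenced from cultured rat smooth muscle cells of the thoracic aorta in 3 groups of 3 libraries. The first group carried an empty vector and received bovine serum albumin (BSA), the carrier control. The second carried the empty vector and received advanced glycation end products (AGEs), sugar-modified proteins that accumulate in diabetes, at 200 µg/mL for 24 h. The last group overexpressed cathepsin D (CTSD), an aspartic protease of the lysosome, and received AGEs. Each library held between 4492980 and 5342332 fragments assigned to genes. Group values below are mean FPKM (fragments per kilobase of gene model, scaled to the assigned fragments of the library) ± SD over n = 3 libraries. Log2 fold changes are differences of mean log2(FPKM + 1), and values written as a fold are ratios of mean FPKM. The sources used here do not say whether the 3 libraries of a group came from separate cultures, so the tests measure a spread between libraries that may be partly technical.

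Ctsd (ENSRNOG00000020206, chromosome 1, 215541542 to 215553451 in the deposited annotation) was high in each of the 3 CTSD libraries and low in the other 6. It stood at 13.0 ± 1.46 FPKM in empty-vector BSA cells, 13.9 ± 0.808 in empty-vector AGEs cells and 199 ± 3.88 in CTSD cells, a 14.3-fold difference between the last 2 groups. The log2 fold change with CTSD under AGEs was 3.75 (SE 0.08, limma adjusted p = 2.29e-09). A change of Ctsd under AGEs alone was not detected (log2 fold change 0.09, SE 0.08, adjusted p = 0.509). The exact two-sided permutation p was 0.1 for the CTSD comparison, the smallest that 3 against 3 libraries can give, and 0.4 for the AGEs comparison.

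Of the 32792 genes in the table, 12002 had a value above 0 in any library, and a gene listed at 0 in this table cannot be read as silent. Housekeeping genes such as B2m, Fth1 and Hprt1 were listed at 0 in all 9 libraries, as were 12 of the 13 protein genes of the mitochondrial genome. Among nuclear-encoded subunits of the respiratory chain and ATP synthase, 30 of 76 (39.5%) were listed at 0, while none of 19 proteasome subunits was. Several smooth muscle genes were also listed at 0 or had few fragments. Myocd, a coactivator of the contractile programme, Spp1 and Mgp were listed at 0, and Myh11, Cnn1 and Des had 24, 37 and 9 fragments over all 9 libraries. Col1a1 and Lgals3 of the synthetic list had 42 and 2, and the matrix gene Bgn had 4. Smtn, of the contractile list, had 2824. Of 20 matched contractile genes 9 could be tested, and of 17 matched synthetic genes 10. Each gene group below is described by its tested members.

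**Figure D1:**
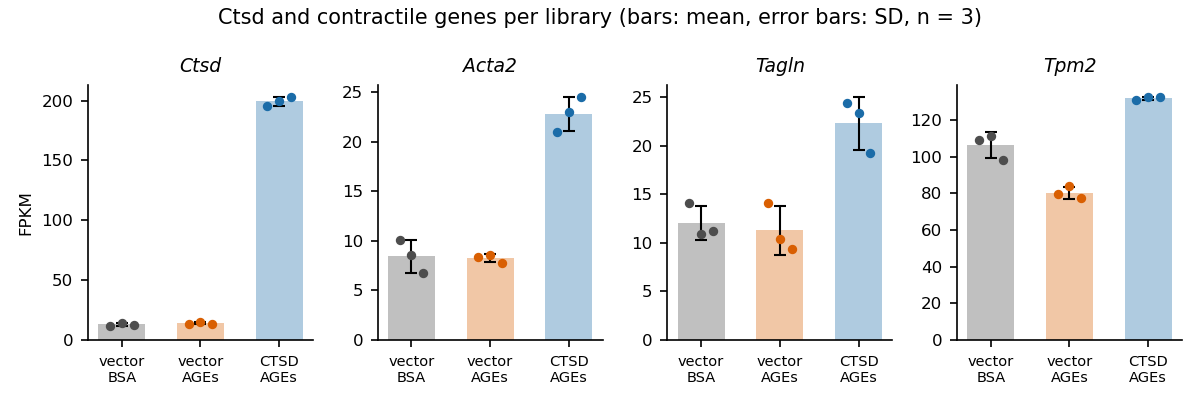
FPKM of Ctsd and of the contractile genes Acta2, Tagln and Tpm2 in the 3 groups (vector BSA, vector AGEs, CTSD AGEs). Bars are group means, error bars SD and points the 3 libraries of a group; Ctsd lies at 199 ± 3.88 FPKM with CTSD against 13.9 ± 0.808 with AGEs alone.

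The comparison of empty-vector AGEs with empty-vector BSA cells asks how AGEs change smooth muscle gene expression. Of 17 tested endoplasmic reticulum stress genes 11 fell (list adjusted p = 0.102 with an estimated correlation), and 6 of 12 hypoxia genes rose (adjusted p = 0.108 with an estimated correlation). The matrix protein gene Thbs1 fell to 0.343 of its BSA level. The transcription factor gene Atf4 (ENSRNOG00000017801), which drives amino acid supply under stress, fell from 434 ± 10.4 to 269 ± 4.37 FPKM. Txnip (ENSRNOG00000021201), which encodes a glucose-responsive inhibitor of thioredoxin, rose 2.85-fold. In all, 1277 of 8532 tested genes passed an adjusted p of 0.05, 516 higher and 761 lower with AGEs, and most changes were small (median size 0.37 log2 units).

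In the endoplasmic reticulum stress list, 11 of 17 tested members fell and 0 rose (13 fell when adjusted over the list alone), with a median log2 fold change of -0.46. The list test (limma camera) gave an adjusted p of 2.17e-08, and an adjusted p of 0.102 with an estimated correlation between genes. Atf4 fell by 0.69 on the log2 scale (SE 0.04, adjusted p = 2.75e-05). Asns, the asparagine synthetase gene that ATF4 activates, went from 20.9 ± 2.42 to 11.99 ± 1.605 FPKM (-0.75, adjusted p = 0.00276). The chaperone gene Hsp90b1 went from 324 ± 7.28 to 201 ± 29.6 FPKM (-0.69, adjusted p = 0.000709). Herpud1, an endoplasmic reticulum degradation gene, had a log2 fold change of -0.56 (adjusted p = 0.00574).

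In the hypoxia list, 6 of 12 members rose and 1 fell, over all genes and adjusted over the list alone alike, with a median of 0.37 (camera adjusted p = 0.00781; adjusted p = 0.108 with an estimated correlation). Egln1, an oxygen-sensing prolyl hydroxylase, rose from 48.2 ± 5.04 to 75.0 ± 3.51 FPKM (0.63, adjusted p = 0.00125). Pdk1, a kinase that inhibits pyruvate dehydrogenase, rose by 0.51 (adjusted p = 0.00682). Adm (0.50, adjusted p = 0.0286) and Ndrg1 (0.48, adjusted p = 0.0297; 0.051 with replicate as a block) passed less securely. Without empty-vector AGEs replicate 2 both had an adjusted p of 0.097.

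In the cell cycle list, 4 of 19 members rose and 0 fell (6 rose when adjusted over the list alone; median 0.13, camera adjusted p = 0.00774, adjusted p = 0.141 with an estimated correlation). The mitotic kinase gene Plk1 rose by 0.33 (adjusted p = 0.00152) and the replication helicase gene Mcm2 by 0.22 (adjusted p = 0.00665). Mcm6 rose by 0.32 (adjusted p = 0.0149; 0.0567 without empty-vector AGEs replicate 1). Cdc20, an activator of mitotic exit, rose by 0.13 (adjusted p = 0.0422; 0.0666 with the block and 0.132 without empty-vector AGEs replicate 1).

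Glycolysis, the pathway the study's title names, had 3 members higher and 1 lower of 17 (4 and 1 when adjusted over the list alone), and its camera adjusted p was 0.369. The median of the list was -0.02, while its mean of 0.01 and the test pointed upward. The glucose transporter gene Slc2a1 rose from 95.3 ± 3.45 to 129 ± 1.40 FPKM (0.43, adjusted p = 0.000523). Aldoa rose by 0.31 (adjusted p = 0.0017), and Pfkm, the muscle phosphofructokinase gene, fell by 0.39 (adjusted p = 0.00263). The other riser, Hk1, gained 0.21 (adjusted p = 0.0406; 0.0618 with the block and up to 0.128 with 1 library left out, here empty-vector BSA replicate 1). Mitochondrial oxidation had 3 of 22 members higher and 1 lower, with the same counts adjusted over the list alone (median 0.03, camera adjusted p = 0.209). The 3 risers, Dlat, Cox5a and Atp5f1b, did not pass with replicate as a block (adjusted p 0.0618, 0.0504 and 0.0583), and Cycs, the cytochrome c gene, fell by 0.34 (adjusted p = 0.00855).

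Of the genes that mark the smooth muscle state, Tpm2, a tropomyosin of the contractile apparatus, fell from 106 ± 7.02 to 80.2 ± 3.23 FPKM (-0.40, adjusted p = 0.00174). It was the 1 contractile gene of 9 to pass (also 1 when adjusted over the list alone), and the list's camera adjusted p was 0.369 with a median of -0.10. In the synthetic list, 3 of 10 fell and 1 rose (6 and 1 when adjusted over the list alone), with a median of -0.35 and a camera adjusted p of 0.0917 (from 0.0317 with no filter on expression, the 1 camera alternative that passed, to 0.222 with a mean FPKM of at least 5). Thbs1 (ENSRNOG00000045829), a matricellular glycoprotein gene, fell from 20.6 ± 1.29 to 7.09 ± 0.556 FPKM (-1.42, SE 0.14, adjusted p = 0.000242). Myh10, a non-muscle myosin gene, went from 30.5 ± 1.00 to 20.7 ± 2.85 FPKM (-0.54, adjusted p = 0.00487). The intermediate filament gene Vim rose by 0.18 (adjusted p = 0.011). Among matrix remodelling genes, 3 of 11 fell and 0 rose (4 when adjusted over the list alone; median -0.06, camera adjusted p = 0.369), with the fibrillar collagen genes Col5a1 at -0.56 (adjusted p = 0.000602) and Col5a2 at -0.52 (adjusted p = 0.0074).

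The remaining lists gave no call for AGEs. In the NRF2 oxidative stress list 3 of 13 rose and 1 fell (4 and 1 when adjusted over the list alone; median 0.03, camera adjusted p = 0.185), among them the peroxiredoxin gene Prdx1 (0.35, adjusted p = 0.0084). Lysosome and autophagy genes other than Ctsd split into 2 higher and 2 lower of 18, also when adjusted over the list alone (median -0.02, camera adjusted p = 0.951), and the autophagy receptor gene Sqstm1 rose by 0.48 (adjusted p = 0.00196). In the inflammation list 1 of 7 rose, Nfkb2 (0.29, adjusted p = 0.00806), also when adjusted over the list alone (median -0.20, camera adjusted p = 0.951). Cholesterol synthesis had 3 of 16 lower and 0 higher, also when adjusted over the list alone (median -0.10, camera adjusted p = 0.37). Those were Idi1 (-0.47), Lss (-0.42) and Cyp51 (-0.23; adjusted p 0.0577 with the block), which lost the call with a library left out, at an adjusted p of up to 0.143, 0.116 and 0.144 (empty-vector AGEs replicate 1 for the first pair, empty-vector BSA replicate 2 for Cyp51). Immediate early and heat shock genes went both ways, 5 up and 3 down of 14 (5 and 5 when adjusted over the list alone). Their median of -0.11 and mean of -0.04 lay below 0 while the test pointed upward (camera adjusted p = 0.506). There the co-chaperone gene Dnajb1 rose by 0.60 (adjusted p = 7.03e-05) and Egr2 went from 13.8 ± 1.64 to 7.003 ± 1.07 FPKM (-0.89, adjusted p = 0.00238).

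Lists with fewer than 5 tested members were counted only, and their counts were the same when adjusted over the list alone. The phosphate transporter gene Slc20a1 fell by 0.34 (adjusted p = 0.00295) among 3 osteogenic genes, and 0 of 4 AGE-binding and 0 of 3 interferon genes passed. For other cell types, 0 endothelial, 0 epithelial or mesothelial and 0 Schwann or neural markers passed the filter on expression. The fibroblast marker Pdgfra (-0.07, adjusted p = 0.793) and the macrophage marker Cd68 (-0.39, adjusted p = 0.467) did not pass the test. Of 3 adipocyte markers the nuclear receptor gene Pparg rose, by 0.27 (adjusted p = 0.004), at 304 ± 10.2 FPKM with AGEs. No gene of the mitochondrial genome could be tested.

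The other genes with the steepest falls included Septin3 (-1.30, adjusted p = 5.88e-05) and Pycr1, a proline synthesis gene, which went from 29.2 ± 3.14 to 11.5 ± 1.14 FPKM (-1.27, adjusted p = 9.34e-05). Ogt, which attaches N-acetylglucosamine to intracellular proteins, went from 18.9 ± 0.382 to 7.36 ± 1.33 FPKM (-1.26, adjusted p = 0.00034). H1f4, a linker histone gene (-1.77), and Crebl2 (-1.23) were also lower. Baiap2, a regulator of actin protrusions, rose from 87.8 ± 11.9 to 144 ± 8.56 FPKM (0.71, adjusted p = 0.0021). Dedd2 (0.88), the arrestin-domain gene Arrdc3 (0.84), Foxs1 (0.79) and Iqcb1 (0.70) rose as well. Further genes met the naming rule on few fragments: Hint2 (0.89) and Gm23187 (-2.14, an 86-base model with at most 3 fragments in a library), which with voom on fragments had an adjusted p of 0.104 and 0.111. The histone gene H2ac20 (-1.59), Pirt (-1.40), LOC688320 (-1.19), Brf2 (0.77; adjusted p 0.0501 with the block), Bmp6 (0.86) and LOC102549061 (0.81) each lost the call in at least 1 fit with a library left out. Their highest adjusted p was 0.115, 0.0728, 0.0546, 0.125, 0.0708 and 0.0626. The libraries left out in those fits were empty-vector AGEs replicate 1 for H2ac20 and Bmp6, empty-vector BSA replicate 1 for LOC102549061, and empty-vector BSA replicate 3 for the others.

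Empty-vector AGEs replicate 3 lay nearest to the BSA libraries. Its mean correlation across genes was 0.9856 with BSA libraries and 0.9864 with its own group, against 0.9838 and 0.9878 for replicate 1. The share of called genes that were higher with AGEs was 40.4% with the deposited scaling, 59.6% with median-of-ratios scaling and 51.7% with quantile normalization, so the balance of rises and falls rests on the scaling. The count of 1277 was 1213 with replicate as a block, 807, 850 and 807 without empty-vector BSA replicate 1, 2 and 3, and 761, 841 and 1607 without empty-vector AGEs replicate 1, 2 and 3. Fold changes with AGEs also followed gene model length (rho -0.157 across genes), with a median of 1823 bases for genes that rose and 2452 for genes that fell. Within the AGEs group, replicate 2 minus replicate 3 had a rho of -0.275 with length. With the length trend removed, 1233 genes passed, 58.9% of them higher with AGEs.

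**Figure D2:**
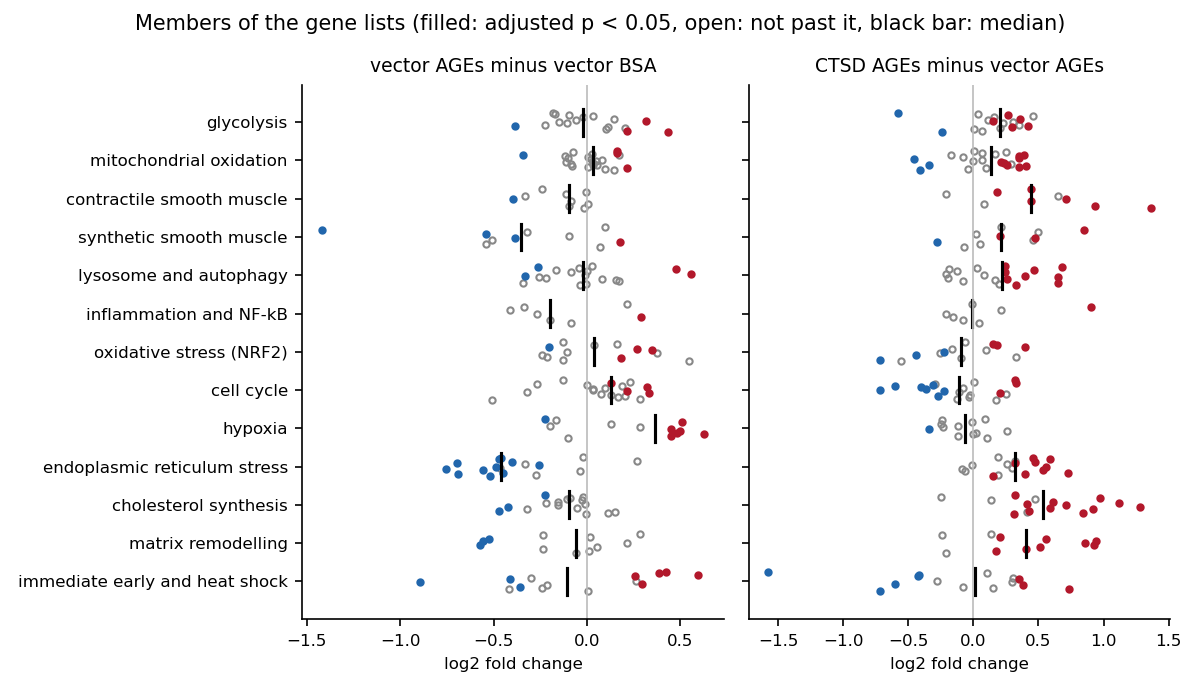
Log2 fold change of each tested member of the gene lists, for AGEs (left) and CTSD overexpression (right). Filled red points rose and filled blue points fell at an adjusted p under 0.05, open points did not pass, and the black bar is the median of the list, -0.46 for endoplasmic reticulum stress with AGEs and 0.53 for cholesterol synthesis with CTSD.

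The comparison of CTSD with empty-vector cells, both under AGEs, asks what cathepsin D does in AGEs-treated smooth muscle cells. Of 9 contractile genes 6 rose (list adjusted p = 0.219 with an estimated correlation): Acta2 (ENSRNOG00000058039), the smooth muscle actin gene, went from 8.25 ± 0.398 to 22.8 ± 1.73 FPKM, a 2.77-fold rise, and Tagln (ENSRNOG00000017628) from 11.3 ± 2.50 to 22.3 ± 2.74. So did 12 of 16 genes of cholesterol synthesis, 8 of 11 of the matrix and 9 of 17 of endoplasmic reticulum stress (list adjusted p = 0.107, 0.186 and 0.192 with an estimated correlation). The constitutive chaperone gene Hspa8 (ENSRNOG00000034066) fell from 1087 ± 44.0 to 369 ± 81.7 FPKM, and the splicing factor gene Srsf1 from 229 ± 8.19 to 88.3 ± 3.30. Of 8532 genes, 2617 passed, 1591 higher and 1026 lower with CTSD (median size 0.43 log2 units).

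Of 9 tested contractile genes, 6 rose and 0 fell, also when adjusted over the list alone, with a median of 0.45 (camera adjusted p = 0.00493; adjusted p = 0.219 with an estimated correlation). Acta2 had a log2 fold change of 1.36 (SE 0.13, adjusted p = 5.17e-05), Tagln of 0.94 (SE 0.16, adjusted p = 0.00129) and Tpm2 of 0.71 (SE 0.06, adjusted p = 1.89e-05). The list names 20 genes, and the others did not pass the filter on expression. Acta2 and Tagln stayed low beside the actin gene Actb, at 16956 to 17666 FPKM in the CTSD libraries. Whether these low levels belong to the cells or to the alignment was not tested. Synthetic genes did not form a call: 3 of 10 rose and 1 fell (5 and 1 when adjusted over the list alone; median 0.21, camera adjusted p = 0.214). Thbs1 rose by 0.85 to 13.8 ± 2.83 FPKM (adjusted p = 0.00117) and Fn1, the fibronectin gene, by 0.47 (adjusted p = 0.00125), while Vim fell by 0.28 (adjusted p = 0.000362).

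In cholesterol synthesis, 12 of 16 members rose and 0 fell (14 rose when adjusted over the list alone), with a median of 0.53 (camera adjusted p = 2.01e-05; adjusted p = 0.107 with an estimated correlation). Lss (ENSRNOG00000054549), which closes the sterol ring, rose 2.63-fold, from 6.78 ± 0.691 to 17.8 ± 1.25 FPKM (log2 fold change 1.28, SE 0.12, adjusted p = 3.71e-05). Insig1, a sterol-sensing regulator, rose by 1.12 (adjusted p = 0.000531), Mvd by 0.97 (adjusted p = 0.000502) and Fdps by 0.92 (adjusted p = 0.000972). Outside the list, Acss2 (ENSRNOG00000018755), which makes acetyl-CoA from acetate, rose 2.74-fold, from 43.1 ± 2.48 to 118 ± 3.53 FPKM (1.43, SE 0.06, adjusted p = 6.61e-07).

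**Figure D3:**
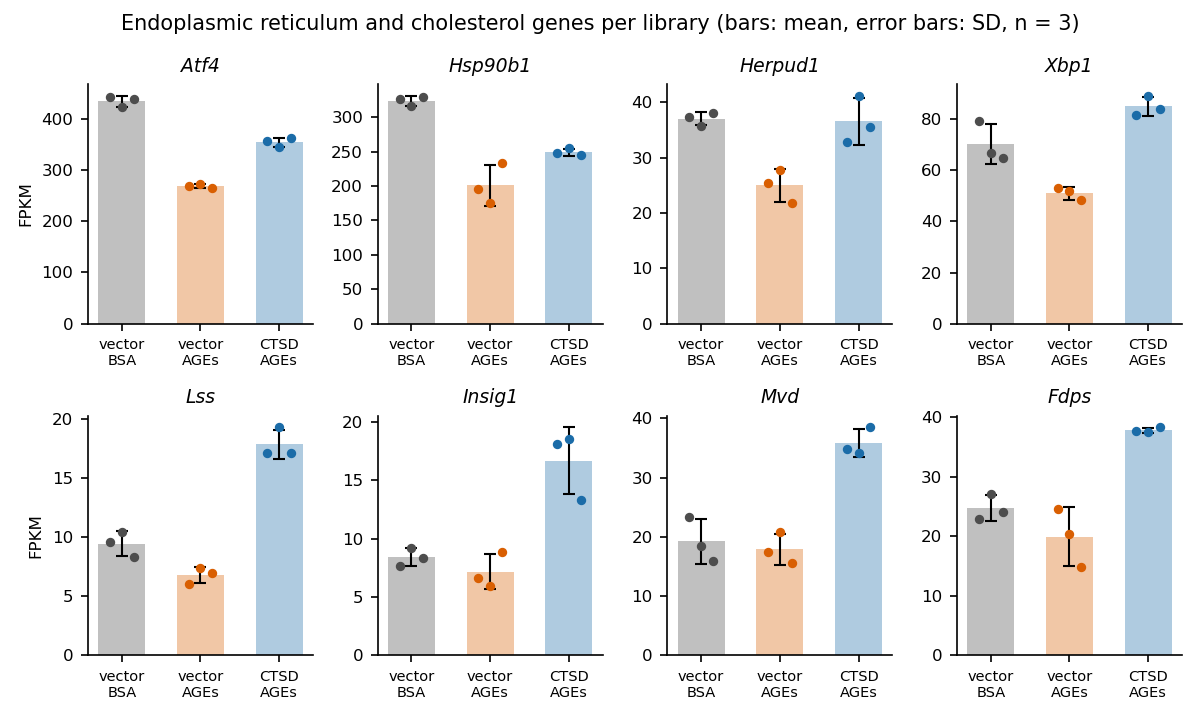
FPKM of endoplasmic reticulum genes (Atf4, Hsp90b1, Herpud1, Xbp1) and cholesterol synthesis genes (Lss, Insig1, Mvd, Fdps) in the 3 groups. Bars are group means, error bars SD and points the 3 libraries of a group; Atf4 lies at 434 ± 10.4 FPKM with BSA and 269 ± 4.37 with AGEs, and Lss at 6.78 ± 0.691 with AGEs and 17.8 ± 1.25 with CTSD.

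The endoplasmic reticulum stress list had 9 of 17 members higher and 0 lower, also when adjusted over the list alone (median 0.32, camera adjusted p = 0.000598, adjusted p = 0.192 with an estimated correlation). Xbp1, a transcription factor of the unfolded protein response, rose from 51.1 ± 2.53 to 85.1 ± 3.77 FPKM (0.72, adjusted p = 0.00011). Manf (0.58, adjusted p = 2.41e-05), Sdf2l1 (0.56, adjusted p = 0.00069) and Herpud1 (0.53, adjusted p = 0.00292) rose too. In matrix remodelling 8 of 11 rose and 0 fell, also when adjusted over the list alone (median 0.41, camera adjusted p = 0.00403, adjusted p = 0.186 with an estimated correlation). The collagen genes Col5a1, at 24.3 ± 0.862 and 47.6 ± 2.54 FPKM (0.94, adjusted p = 8.99e-06), and Col4a1 (0.86, adjusted p = 0.00115) rose, as did the crosslinking enzyme gene Loxl2 (0.92, adjusted p = 0.00141).

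Cell cycle members went both ways, 3 higher and 7 lower of 19 (3 and 8 when adjusted over the list alone), with a median of -0.11. The camera adjusted p was 0.0402, with an adjusted p of 0.219 with an estimated correlation and 0.147 once a trend with gene density was removed. The 4 members that fell furthest serve DNA replication: Mcm3 (-0.72, adjusted p = 0.000553), Pcna (188 ± 2.66 to 124 ± 11.4 FPKM, log2 fold change -0.60, adjusted p = 6.33e-05), Mcm6 (-0.41, adjusted p = 0.00183) and Mcm4 (-0.37, adjusted p = 0.0038). Replication genes were not tested as a list. Among the 3 that rose were the mitotic genes Cdc20 (0.32, adjusted p = 0.000131) and Plk1 (0.21, adjusted p = 0.00612), given here after their values were seen.

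Glycolysis genes were higher more often than lower with CTSD, 5 and 2 of 17 (6 and 2 when adjusted over the list alone), with a median of 0.20. The list test did not pass (camera adjusted p = 0.0576), and over its camera alternatives the adjusted p ran from 0.0196 with no filter on expression to 0.329 with an estimated correlation. It passed with no filter and with quantile normalization (0.0419), and not with median-of-ratios scaling (0.117), the density trend removed (0.176) or without empty-vector AGEs replicate 3 (0.124). The phosphofructokinase genes Pfkm (0.42, adjusted p = 0.000545) and Pfkl (0.29, adjusted p = 0.00459; 0.172 with the density trend removed) and the phosphoglycerate mutase gene Pgam1 (0.36, adjusted p = 0.000288) rose. The lactate transporter gene Slc16a1 fell from 32.2 ± 0.469 to 21.3 ± 2.25 FPKM (-0.58, adjusted p = 0.000733). The other member that fell was Slc2a1, from 129 ± 1.40 to 109 ± 4.66 FPKM (-0.24, adjusted p = 0.00384), given here after its values were seen. Mitochondrial oxidation had 8 of 22 members higher and 3 lower (8 and 4 when adjusted over the list alone; median 0.13, camera adjusted p = 0.214). Cycs rose by 0.39 (adjusted p = 0.0017), while the complex I gene Ndufs1 (-0.46, adjusted p = 0.00103) and the pyruvate dehydrogenase gene Pdha1 (-0.41, adjusted p = 0.00118) fell.

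Lysosome and autophagy genes other than Ctsd had 9 of 18 members higher and 0 lower (9 and 1 when adjusted over the list alone; median 0.22). Their camera adjusted p was 0.0576, and over the camera alternatives it ran from 0.0196 with no filter to 0.329 with an estimated correlation. It passed with no filter, a mean FPKM of at least 5 (0.0425), quantile normalization (0.0455) and removal of a length trend (0.0473), and not with median-of-ratios scaling (0.0762), the density trend removed (0.147) or without empty-vector AGEs replicate 3 (0.124). Gabarapl1, an autophagosome protein gene, rose from 73.3 ± 6.80 to 118 ± 1.93 FPKM (0.68, adjusted p = 6.64e-05). The hexosaminidase gene Hexa (0.65, adjusted p = 0.00372) and the proton pump gene Atp6ap1 (0.46, adjusted p = 0.000281) rose, and so did the protease gene Ctsf (0.65, adjusted p = 0.0159; 0.0592 without CTSD replicate 1 and 0.0638 with the density trend removed).

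The other lists gave no call for CTSD. Of 4 genes that bind or clear AGEs, 3 rose, also when adjusted over the list alone, among them the scavenger receptor gene Scarb1 (27.1 ± 2.20 to 42.3 ± 0.786 FPKM, log2 fold change 0.62, adjusted p = 0.000154), Hagh (0.47, adjusted p = 0.00739; 0.129 with the density trend removed) and Ddost (0.36, adjusted p = 0.00592). In the NRF2 list 3 of 13 rose and 3 fell, also when adjusted over the list alone (median -0.10, camera adjusted p = 0.411), with the glutathione synthesis gene Gclc at -0.72 (adjusted p = 0.000696). In the hypoxia list 0 rose and 1 of 12 fell, P4ha1 (-0.34, adjusted p = 0.00209), also when adjusted over the list alone (median -0.07, camera adjusted p = 0.244). In the inflammation list 1 of 7 rose, the cytokine gene Lif (0.90, adjusted p = 0.00205), also when adjusted over the list alone. That list's median of -0.01 and the test pointed down while its mean was 0.10 (camera adjusted p = 0.916). Immediate early and heat shock genes had 3 of 14 higher and 5 lower, also when adjusted over the list alone. Their median was 0.01 while the mean of -0.13 and the test pointed down (camera adjusted p = 0.214), and Egr1 fell by 0.60 (adjusted p = 1.42e-05). Of 3 osteogenic genes 0 passed. The interferon gene Irf1 rose, 1 of 3, by 0.28 (adjusted p = 0.0427; 0.147 without empty-vector AGEs replicate 1). Among other cell types' markers Pparg rose by 0.37 to 394 ± 12.2 FPKM (adjusted p = 0.000199), 1 of 3 adipocyte markers, while Pdgfra (0.16, adjusted p = 0.451) and Cd68 (0.66, adjusted p = 0.163) did not pass. Endothelial, epithelial or mesothelial, Schwann or neural and mitochondrial-genome lists had 0 tested members here too.

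Among single genes, Hspa8 had the steepest named fall (-1.58, SE 0.12, adjusted p = 1.25e-05). LOC680121 (-1.33), LOC688932 (-1.23) and LOC688655 (-1.21) are annotated as similar to heat shock protein 8, so their fragments may be shared with Hspa8 and the 4 falls are not separate observations. Srsf1 (ENSRNOG00000050323) fell by 1.36 (SE 0.05, adjusted p = 2.77e-07), and the mRNA export gene Thoc5 from 105 ± 2.52 to 43.2 ± 2.79 FPKM (-1.27, adjusted p = 6.61e-07). The exosome gene Exosc9 (-1.19), Spata5 (-1.12) and Lin9 (-1.11) were lower. The endoplasmic reticulum export gene Cnih2 rose from 11.2 ± 0.822 to 28.9 ± 4.35 FPKM (1.29, adjusted p = 7.38e-05). Slc22a17 (1.24), the autophagy gene Tp53inp2 (1.23) and Cryl1 (1.30) rose too. LOC688320 (1.35), Gm27401 (1.29) and Mir2861 (-1.30) met the naming rule on at most 13, 11 and 7 fragments in a library. The call for Mir2861 had an adjusted p of 0.147 without CTSD replicate 2.

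The share of called genes that were higher with CTSD was 60.8% with the deposited scaling and 48.1% with median-of-ratios scaling, so this balance too rests on the scaling. Fold changes with CTSD followed the number of genes within 0.5 Mb (rho 0.28 across genes, which are not independent replicates). The median number, which includes the gene itself, was 30 for genes that rose and 16 for genes that fell.

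A further question is how far CTSD moved the genes that AGEs had moved. Both comparisons passed in opposite directions for 626 genes, and in the same direction for 78. Of the 626, 407 fell with AGEs and were higher with CTSD, among them Acss2, Thbs1, Col5a1, Xbp1 and Herpud1, and 219 rose with AGEs and were lower with CTSD, among them Slc2a1 and Dnajb1. Acss2, for example, stood at 80.7 ± 4.81 FPKM with BSA, 43.1 ± 2.48 with AGEs and 118 ± 3.53 with CTSD. By contrast, Ogt stayed low, at 7.36 ± 1.33 FPKM with AGEs and 7.63 ± 1.04 with CTSD, and Txnip stayed high, at 10.1 ± 1.27 and 11 ± 0.748. Lists of these sizes drawn independently would share 204 genes in opposite directions and 188 in the same direction.

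The comparisons share the 3 empty-vector AGEs libraries with opposite sign, which builds in a negative relation. Across genes the fold changes had r = -0.369, weaker than the median of -0.502 in 100 simulations of unchanged groups. Their covariance was -0.038, larger in size than the simulated range of -0.0204 to -0.013. Those simulations assume equal and independent noise and may understate that of the AGEs libraries, so noise is not excluded. The simulations called 0 genes in both comparisons, a count that unchanged groups nearly always give at an adjusted p under 0.05. With fold changes computed from disjoint AGEs libraries the covariance averaged -0.0157 (range -0.0305 to 0.00503), and the count of 626 was 405 without empty-vector BSA replicate 3 and 384 without empty-vector AGEs replicate 1.

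**Figure D4:**
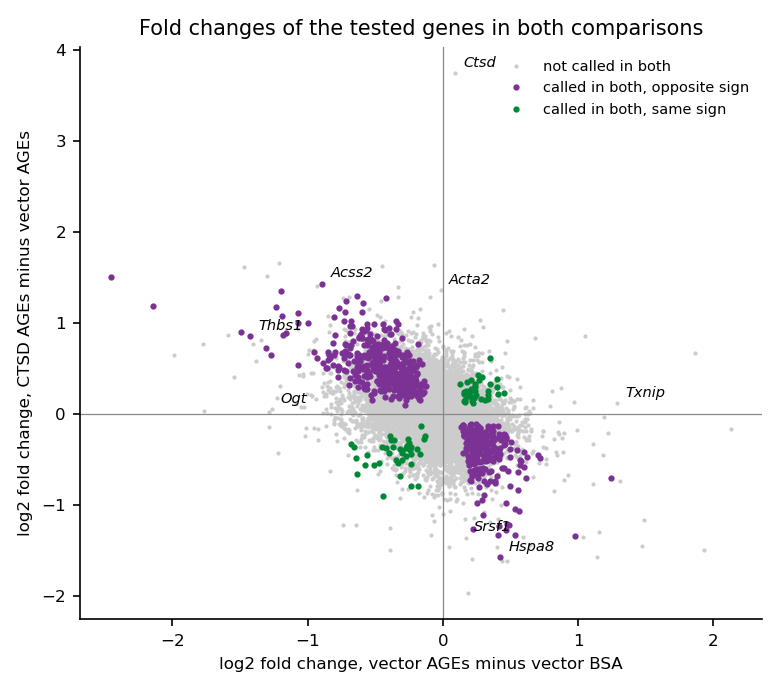
Log2 fold change of each tested gene with AGEs (x axis) and with CTSD overexpression under AGEs (y axis). Purple points passed in both comparisons with opposite sign (626 genes), green points with the same sign (78 genes), and grey points did not pass in both.

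Against empty-vector BSA cells, CTSD cells under AGEs differed in expression. CTSD and AGEs change together in this contrast, and no CTSD group with BSA was analysed here. The differences can thus not be assigned to either of them. Cholesterol synthesis was higher than in BSA cells, with 11 of 16 members up and 0 down (median 0.49, camera adjusted p = 0.000143; adjusted p = 0.158 with an estimated correlation). Contractile genes were higher as well, 5 of 9 (median 0.31, camera adjusted p = 0.0157; adjusted p = 0.253 with an estimated correlation), with Acta2 at 8.46 ± 1.67 FPKM in BSA cells (log2 fold change 1.35, adjusted p = 8.97e-05). Glycolysis had 7 of 17 members higher and 1 lower (median 0.16, camera adjusted p = 0.0156), lysosome and autophagy 8 and 1 of 18 (median 0.28, camera adjusted p = 0.0157), each with an adjusted p of 0.253 with an estimated correlation. Mitochondrial oxidation had 9 and 3 of 22 (median 0.17, camera adjusted p = 0.0188) and matrix remodelling 5 and 1 of 11 (median 0.22, camera adjusted p = 0.0162), again each at an adjusted p of 0.253 with an estimated correlation. Adjusted over the list alone, the risers and fallers were 8 and 1 for glycolysis, 11 and 3 for mitochondrial oxidation and 7 and 2 for matrix remodelling, and as above for the others.

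Endoplasmic reticulum stress genes were no longer called as a list against BSA (1 higher, 5 lower of 17; median -0.07, camera adjusted p = 0.33), and Atf4 was at 354 ± 8.78 FPKM, still lower than with BSA (-0.29, adjusted p = 0.00038). Ogt (-1.21, adjusted p = 0.000169) and Srsf1 (-1.19, adjusted p = 8.14e-07) were lower and Txnip (1.40, adjusted p = 5.5e-05) higher than with BSA. In total 2782 genes passed, 1394 higher and 1388 lower. Of the 626 genes with opposite changes, 210 (33.5%) passed against BSA, a share close to that of all tested genes (2782 of 8532). Of the 210, 44 lay on the side to which AGEs had moved them and 166, such as Acss2 (0.54, adjusted p = 2e-04), beyond the BSA level. A gene that did not pass is not thereby shown to be back at the BSA level.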

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

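Limma voom, the filter on gene model length, the removal of length and density trends, and the list tests without empty-vector AGEs replicate 3 were chosen after the result was seen. The negative binomial models were planned for deposited raw counts and were not run, since the deposited unit is FPKM. Voom on the recovered fragments was run instead. Fits of 2 groups alone give no value for the opposite changes. No named gene's call reversed under any alternative run. The share of rises among called genes crossed 50% for both contrasts with median-of-ratios scaling, as given in the report. With the density trend removed, 1946 of the 1947 CTSD genes also called before kept their sign. Of the lists not called, lysosome and autophagy (AGEs) and inflammation (AGEs and CTSD) changed the sign of their test in at least 1 alternative. The counts of called genes stayed within 1.5 times the reported ones under every alternative that kept all libraries of the contrast: 936 (2-group fit) to 1546 (voom) for AGEs, and 2294 (density trend removed) to 2756 (voom) for CTSD. With 1 library left out, the AGEs count ranged from 761 to 1607, and the count of opposite changes from 384 to 629, in fits with fewer libraries. The number of lists called went from 3 to 0 for AGEs and from 5 to 0 for CTSD with an estimated correlation, and to 6 and 12 with fry, which does not compare a list with other genes. The replicate block changed no list call. Of the named calls, 36 of 65 for AGEs and, besides Ctsd, 56 of 67 for CTSD held under every alternative that could test them. The block ended 12 AGEs calls, among them Hk1, Dlat, Cox5a, Atp5f1b, Cdc20 and Ndrg1, whose values are in the report, and Brf2 (adjusted p 0.0501), Tfeb (0.0641), Gclm (0.0631), Cyp51 (0.0577) and Loxl2 (0.0573). It also ended the CTSD calls of Mir2861 (0.0691), Cat (0.0584) and Irf1 (0.0691). Fn1, called with AGEs at -0.39, had an adjusted p of 0.224 with the length trend removed, and Irf1 passed with AGEs under quantile normalization (0.0359); the cause was not tested. The Ctsd fold change with CTSD kept its direction and its call under every alternative run. At 4492980 to 5342332 assigned fragments per library, genes with few fragments, such as Gm23187 and Hint2, which voom did not call, have the least certain fold changes.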

Other observations

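The tests of symbol families, mitochondrial and multiply matching reads, disjoint libraries and gene density were chosen after the result was seen, as were the bounds for the shared libraries, the scaling offset and the splits, whose fits were planned; the bound for a density trend as the whole cause was set before its count was seen. Genes that share the first 4 letters of their symbol were tested as families, 72 families with at least 10 tested members. With CTSD, 13 of 18 Hnrn genes (heterogeneous nuclear ribonucleoproteins) fell and 1 rose, with a median log2 fold change of -0.27 (camera adjusted p 4.74e-06, and an adjusted p of 0.556 with an estimated correlation). Of 10 Srsf genes (serine and arginine rich splicing factors), 6 fell and 0 rose, with a median of -0.42 (adjusted p 4.47e-05, and 0.165 with an estimated correlation). Other splicing families did not pass: Snrp had 3 higher and 2 lower of 11 (adjusted p 0.984), and Prpf 2 higher and 5 lower of 13 (adjusted p 0.34). Hnrnpm fell from 491 to 289 mean FPKM (-0.76), Hnrnpu had a log2 fold change of -0.73 and Srsf6 one of -1.03. Of 14 Psmd genes, subunits of the proteasome cap, 8 rose and 0 fell with AGEs (median 0.20, adjusted p 3.07e-05, and 0.318 with an estimated correlation). With CTSD 8 fell and 1 rose (median -0.16, adjusted p 0.00329, and 0.556 with an estimated correlation), in a contrast that shares the AGEs libraries with opposite sign. With AGEs the Hnrn (7 up, 3 down), Psmb (3 up), Ube2 (8 up) and Mrps (1 up) families also passed. These medians kept their sign under median-of-ratios scaling and quantile normalization. With an estimated correlation the other 4 AGEs families had an adjusted p of 0.766.

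Ubiquitous genes listed at 0 in all 9 libraries were the first pattern weighed. Removal of mitochondrial reads as the whole cause is argued against by 13 nuclear-encoded subunits without a named pseudogene that were also at 0. If discarding of reads that match several places were the whole cause, the same 13 subunits should have had values above 0. They cannot decide it, since only pseudogenes named with the suffix -ps were counted and the 13 may have others. Ribosomal protein genes, rich in pseudogenes, were at 0 in 14.8% of cases against 39.5% of respiratory chain and ATP synthase subunits. However, the 12 ribosomal protein genes at 0 each had a named pseudogene, as did Fth1 and Hprt1, so discarding may account for part of the zeros. Actb and Rplp0, which also have a named pseudogene, were not at 0. Reads aligned to a genome of another species may remain a candidate cause. Of fast-evolving genes 39.3% had under 3 fragments, against 0 of 29 slow-evolving genes (Fisher's exact p 0.000116, two-sided). The medians of these lists were 11 and 14031 fragments over all 9 libraries. The authors' notes also name a mouse build, while the deposited identifiers are those of rat. However, the share lay between the bounds of 50% and 20% set in advance, and genes that evolve fast can also be less expressed. Whether genes above 0 also lost fragments was not tested. No biological explanation was tested.

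The opposite changes under AGEs and CTSD were the second. The covariance of -0.038, outside the simulated range, argues against noise in the shared AGEs libraries as the whole cause. However, the simulations assume equal and independent noise. Fragments differed between replicates by a chi-square per degree of freedom of up to 6.77 with AGEs and at most 3.88 in the other groups. The simulated noise of the shared libraries may thus be too small, so noise is not excluded. The correlation of -0.369 was weaker than in each simulation (-0.575 to -0.445). The covariance from disjoint libraries, -0.0157 on average, reached above 0 in 1 of 6 splits. A scaling offset of the AGEs libraries is argued against by the 614 genes that passed with opposite sign after median-of-ratios scaling, against 626. Part of the covariance came from the shared libraries, since each disjoint split gave a smaller size, at most -0.0305 against -0.038. An effect of CTSD on genes that AGEs change stays open, since no CTSD group with BSA was analysed here.

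The link between CTSD fold changes and gene density was the third. A density trend as the whole cause of the calls is argued against by the 2294 genes that passed once the trend was removed (rho -0.002), of which 1947 had also passed before. Between libraries of 1 group the density correlation reached 0.233, in a pair with empty-vector AGEs replicate 3, and pairs within the BSA and CTSD groups stayed at 0.03 or less in size. The contrast of CTSD with BSA, which does not use that library, had a rho of 0.332, against 0.28 for CTSD under AGEs. A bias in library preparation that follows base composition and differs between groups cannot be told apart from an effect of CTSD, because no genome sequence was used to measure base composition.

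For each contrast, all 10 splits of the 6 libraries into 3 and 3 were fitted. The real split gave 1277, 2617 and 2782 genes for AGEs, CTSD and CTSD against BSA, the counts of the fit to all 9 libraries. The highest other split gave 0, 1 and 1, and 1 split of 10, the real one, gave as many genes. Every other split mixes the groups, which puts any group difference into the spread, so low counts there were built in. Among the 4 AGEs splits that part all 3 replicate numbers, the highest other was also 0. With 10 splits the share cannot go under 1 of 10, so it cannot reach 0.05.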
